A study of Homo sapiens with 4 samples.

How the data were processed

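Plasmid DNA of ChIP-STARR-seq reporter libraries from human neural stem cells was sequenced in 4 samples, 2 of a library made from H3K27ac and H3K4me1 ChIP DNA (HIST) and 2 of a library made from SOX2 and YY1 ChIP DNA (TF). Per the labels' protocols, adaptor-ligated ChIP DNA was amplified replicate by replicate, joined to the STARR-seq plasmid by Gibson assembly, pooled over ChIP replicates before electroporation into bacteria, and recovered as plasmid DNA after growth. As described there, the fragments of a library were pooled before the plasmid DNA was sampled, and nothing in the labels says that they came from separate cell cultures. Per the submitters' processing notes, the genome build was GRCh38 (hg38) and the tools included Trimmomatic 0.39, Bowtie2 2.4.2, Picard, deepTools 3.4.3, MACS2 2.1.2 and bedtools 2.30.0. The role and order of these tools, the control of the peak caller, its thresholds and the way the consensus of the replicates was made are not given in the sources used here.

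The authors deposited 1 list per library in the 10-column narrowPeak layout that MACS2 writes, with no header. Region names in the lists say that the peaks of each plasmid library were merged, so no value per replicate could be compared. The authors' values used here were the fold enrichment at each summit, a ratio over the background of the peak caller, and the −log10 of the q-value of each region; the deposited −log10 p-value served only to check the column order. Column 10 was read as the summit position in bp from the region start, as deposited. These values come from the layout and the ranges of the columns, and they were used only to describe, rank or filter regions within a list. The lowest −log10 q was 1.30 in the HIST list and 1.39 in the TF list. The smallest width was 176 bp in the HIST list, shared by 15.3% of its regions, and 144 bp in the TF list, shared by 9.57%, so the lists differ in their smallest width. The lists carry no read counts, so depth per sample is unknown, and a region missing from a list was not necessarily missing from the plasmids. A longer list reaches weaker regions, and ChIP fragments, amplification and cloning all act on which fragments a plasmid pool holds; the intervals given here cover only the sampling of genome blocks or genes.

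Regions on chromosomes 1 to 22 entered the main comparisons. Overlap was counted at 1 bp or more, and a count by bedtools 2.31.1 on chromosome 1 gave the same numbers under all 3 overlap rules. For comparison, each list was placed at random 1000 times with bedtools shuffle, keeping chromosome and width and without overlap within the list; assembly gaps were not left out, since no genome sequence was used here. Intervals are 95% limits from 1000 bootstrap draws of 5-Mb genome blocks, since neighbouring regions are not independent. Genes were the 19126 autosomal protein-coding genes of NCBI's table for GRCh38.p14, the build of the lists apart from patches, and gene names come from that table. It gives no strand and no exons, so the planned transcription start sites were replaced by both annotated ends of each gene (1 kb either side), and the planned exon and intron classes by gene end, gene body and intergenic. A gene end is therefore a start or a stop of a gene. Covered sequence per gene was counted in the gene body extended by 10 kb on each side; such windows overlap between neighbouring genes. Chromosome lengths came from GenomeInfoDb 1.38.1 in R 4.3.3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

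With 1 list per library there is no p-value across regions or genes. Each of 21 gene lists was placed among 10000 random lists of the same size and the same deciles of gene length, and counted as above or below the random range beyond percentiles 97.5 and 2.5. The 126 pairs of list and measure would give 6.3 beyond these limits by chance, and 68 were beyond them. The 6.3 assumes independent genes, whereas members of clustered families share regions. Some lists also share members, and some measures are computed from others, so the pairs are not independent. The measures per list were the share of genes with a region at an end and the mean covered sequence in each library, the TF minus HIST difference in the former, and the TF share of TF plus HIST sequence. Shares of genes carry exact Clopper-Pearson intervals where given. Genes were named by a rule fixed before the data were examined: SOX2 and YY1; per list, the up to 4 genes with the most HIST sequence, the up to 4 with the most TF sequence and up to 4 with a TF but no HIST region at an end; and over all genes the 10 with the most HIST sequence, with the most TF sequence and with the most TF sequence outside HIST regions. The rule gave 168 genes, of which those described are a part. Genes on other chromosomes were not named. Genes over the largest clusters, and genes at the strongest regions, are named as the annotation of those regions.

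The overlap step was tested on simulated data. With overlap planted in 10% and 50% of 23638 TF-like regions it returned 11.7% and 50.9%, since some of the rest overlapped by chance. For gene lists, the TF list was first placed at random. In each of 50 lists of 40 genes, 12 genes were then marked as having a TF region at an end. Of these lists, 100% passed the upper limit for TF gene ends. Without the marks, 2% of the 50 lists passed either limit, with 19126 genes in the table. In the real TF list, 31.0% of all genes had a region at an end. The test with marked genes therefore does not show how small a difference would be found in these data. It checks only the ranking of a list among random lists, not the matching of regions to gene ends. The alternatives tried were other overlap rules, the 50% of each list with the higher −log10 q, regions of at least 200 bp, chromosome X added, regions merged first, other windows around gene ends and genes, ends of all 56742 annotated genes, shares in bp, random lists not matched on length, and other cluster distances. Alternatives chosen after seeing the data were moving TF regions by up to 1 Mb, 200 bp around each summit, a HIST list reduced to the TF number by highest −log10 q, and gene lists without the member with the most sequence. Clusters were also compared with 200 random placements of each list. Motif content was planned and not run, since no genome sequence was used here.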

Results

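The plasmid libraries of a ChIP-STARR-seq experiment in human neural stem cells were sequenced as DNA. In ChIP-STARR-seq, genomic fragments recovered by chromatin immunoprecipitation are cloned into the transcribed part of a reporter plasmid, so the plasmid pool defines which sequences can be assayed. The 4 samples formed 2 libraries of 2 replicate samples each. The HIST library held fragments precipitated with H3K27ac, a mark of active promoters and enhancers, and with H3K4me1, a mark of enhancers. The TF library held fragments precipitated with SOX2, an HMG-box transcription factor of neural stem cells, and with YY1, a zinc finger transcription factor that binds many promoters. The values analysed here were 1 consensus list of regions per library. Neither list gives values per replicate, so the comparisons below describe these lists and have no replicate check. The HIST list held 88951 regions and the TF list 24281, of which 87631 and 23638 lay on chromosomes 1 to 22 and entered the comparisons. The lists hold no read counts, so the sequencing depth behind them is unknown.

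The first comparison asked which parts of the genome each library carried. HIST sequence was most abundant at GSE1 on chromosome 16, where 249 regions covered 112327 bp of the gene and its 10-kb flanks. ZMIZ1, a transcriptional co-regulator, followed with 59065 bp in 130 regions, and MSI2, an RNA-binding protein of stem and progenitor cells, with 58716 bp in 154 regions. The genes with the most TF sequence were RAD51B, a DNA repair gene, with 9212 bp in 28 regions, ZFHX3, a homeobox and zinc finger transcription factor, with 8247 bp in 28 regions, and NAV2, a neuron navigator, with 7474 bp in 25 regions. GSE1, MSI2, NAV2, ZFHX3 and KAZN were among the 10 genes with the most covered sequence in both libraries. SOX5, a SOX family transcription factor, had rank 4 for TF sequence with 7378 bp, of which 5168 bp lay outside HIST regions, beside 13222 bp of HIST sequence. WWOX had the most TF sequence outside HIST regions, 5265 of 5689 bp, followed by MACROD2 with 5189 of 6700 bp. Counts per gene grow with gene length, and these genes are long.

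HIST regions also formed longer runs than TF regions. Joined across short gaps, at a distance between the 5 and 25 kb tried as alternatives, they made 29305 clusters, of which 1491 held 10 or more regions and together 30.8% of all HIST regions. TF regions made 16925 clusters, 73.6% of them a single region, and 11 clusters held 10 or more, with 0.529% of all TF regions. A longer list joins more readily at a fixed distance, and randomly placed HIST regions gave 16.2 ± 4.00 such clusters (SD over 200 placements). With HIST reduced to the number of TF regions, an alternative chosen after seeing the data, 146 of 12471 clusters held 10 or more regions. They held 8.82% of all regions, against 0 such clusters in the placements of either list. The placements moved each region on its own, so wider domains called as several neighbouring regions would exceed them too. Whether HIST regions are pieces of such domains was not tested. The HIST cluster with the most covered sequence spanned 85110858 to 85664877 on chromosome 16, over GSE1 and CIBAR2, with 274 regions and 119750 bp. The next HIST clusters lay over CCNK and CCDC85C on chromosome 14 (54869 bp), RAI1 and SREBF1 on chromosome 17 (52885 bp) and AHDC1 on chromosome 1 (51093 bp). A HIST cluster over NOTCH1, the Notch receptor, and EGFL7 on chromosome 9 had rank 6 with 98 regions and 46898 bp. Among TF clusters, the one around SOX2 on chromosome 3 had rank 5, from 181710083 to 181756979, with 11 regions and 3242 bp. TF clusters over URM1 (5349 bp), ZFHX3 (3860 bp) and SKIDA1 and MLLT10 (3743 bp) ranked above it. First among TF clusters was a stretch without protein-coding genes at 46380846 to 46401627 on chromosome 16, with 14 regions and 5579 bp. No list of high-signal artefact regions was used here, so this stretch may be an artefact rather than a bound locus. HIST regions covered 28.5 Mb, 0.991% of the autosomes, with a median width of 253 bp, and TF regions 6.43 Mb, 0.224%, with a median width of 227 bp. The median fold enrichment at the summit, the authors' own value per region, was 5.20 in the HIST list and 6.57 in the TF list, and the highest values were 24.6 and 100.2. Cut to regions of at least 200 bp, the TF list fell to 14415 regions.

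The second comparison asked how far the libraries carried the same sequences. At SOX2 (chromosome 3, 181711925 to 181714436), 9 HIST regions covering 5094 bp and 4 TF regions covering 1464 bp lay in the gene and its 10-kb flanks. A TF region at 181710397 to 181711101, 11.6-fold enriched, overlapped a HIST region at 181710650 to 181711587, also 11.6-fold, just before the gene. The other 3 TF regions there overlapped no HIST region, and 1012 of the 1464 TF bp lay outside HIST regions. At YY1 (chromosome 14, 100239144 to 100282788), 3 TF regions lay within the gene close to its lower-coordinate end, the strongest at 100239844 to 100240186 with 45.4-fold enrichment. None of them overlapped any of the 3 HIST regions at YY1. At NES, the nestin gene of neural progenitors, the libraries coincided more closely: 8 TF regions covered 2498 bp, of which 571 bp lay outside the 17 HIST regions. HIST regions covered 13645 bp at NES, against 5094 bp at SOX2 and 856 bp at YY1, and denser HIST coverage by itself raises the overlap.

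Over the autosomes, 11448 of the 23638 TF regions, 48.4% (95% interval 47.4 to 49.4 from a bootstrap of 5-Mb blocks), overlapped a HIST region by at least 1 bp. In 1000 random placements of TF regions on the same chromosomes, 1.84% ± 0.0863 (SD) did, and none of the placements reached the observed share. From the other side, 11994 HIST regions, 13.7% (13.4 to 14.0), overlapped a TF region, against 0.505% ± 0.0243 of randomly placed HIST regions. In base pairs, 2.16 Mb was shared, which was 33.6% of TF and 7.58% of HIST sequence. TF regions at gene ends overlapped HIST regions in 53.9% of cases and TF regions elsewhere in 46.5%. HIST regions at gene ends overlapped TF regions in 25.9% of cases and HIST regions elsewhere in 11.4%. The share of TF regions counted as overlapping fell to 30.3% when at least 50% of the TF region had to be covered, 15.6% with reciprocal overlap of 50%, 31.0% for 200 bp around each summit and 27.0% for a HIST list reduced to the length of the TF list. The HIST share fell to 5.81% and 4.22% under the 50% and reciprocal rules, and every one of these shares stayed above all placements run beside it.

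**Figure D1:**
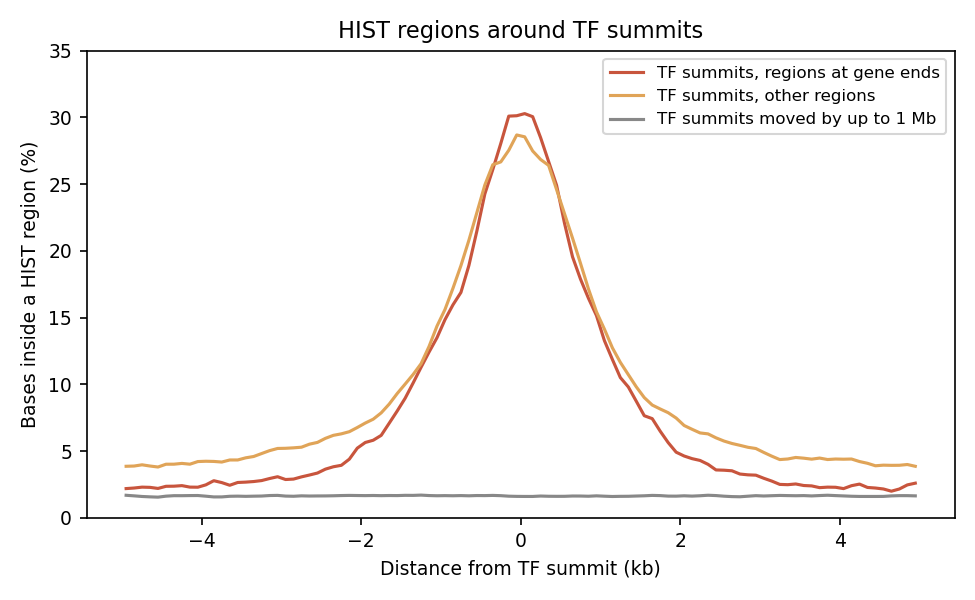
Share of bases inside a HIST region (%) by distance from the TF summit (kb), for TF regions at gene ends, TF regions over 1 kb from any gene end, and TF summits moved by up to 1 Mb. HIST regions covered 30.2% of bases at summits near gene ends, 28.6% at other summits and 1.61% at moved summits.

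HIST coverage was centred on TF summits. At the summit, 30.2% of bases at gene ends and 28.6% elsewhere lay in a HIST region, and 4950 bp before it 2.19% and 3.86% did. TF summits moved by up to 1 Mb had 1.61%.

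The third comparison asked where the regions lay relative to protein-coding genes. The 3 strongest TF regions, named here after their values were seen, lay at ends of USP31 (chromosome 16, 23149429 to 23149840, 100.2-fold), of CXXC1 (chromosome 18, 50287626 to 50288284, 85.7-fold), which encodes a protein that binds unmethylated CpG, and of FUZ (chromosome 19, 49813095 to 49813841, 83.1-fold), which acts in cilium formation. The USP31 and CXXC1 regions overlapped no HIST region. The next TF regions by fold lay far from gene ends, 27001 bp from PAX8 (79.3-fold) and 64020 bp from TRIM43 (75.04-fold). Both overlapped a HIST region, and whether they are high-signal artefacts was not tested. The strongest HIST region, 24.6-fold, lay 181 bp from an end of TCF3, an E-protein transcription factor, at 1652654 to 1652939 on chromosome 19, and the next 4 lay 4965 to 47732 bp from the nearest end, those of TRMT61A, SOCS3 and MYH9. A higher share of TF than of HIST regions lay within 1 kb of an annotated gene end, 26.1% (6160 regions, interval 24.6 to 27.5) against 15.6% (13683 regions, 14.7 to 16.6). Random placements gave 2.96% for TF and 3.13% for HIST regions. The difference was 10.5 percentage points (9.72 to 11.2). By midpoint, TF regions were rarer than HIST regions in gene bodies, 40.1% against 52.3%, a difference of -12.2 points (-13.1 to -11.4), where the autosomes have 40.7%. Intergenic shares were close, 34.6% for TF and 33.5% for HIST, a difference of 1.08 points (0.275 to 1.91). With a HIST list reduced to the length of the TF list, the gene end difference fell to 5.94 points (5.02 to 6.87) and the intergenic difference grew to 3.95 points (2.86 to 5.04). Counted in bp, the intergenic difference was not told apart from 0 (0.177 points, -0.770 to 1.15).

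**Figure D2:**
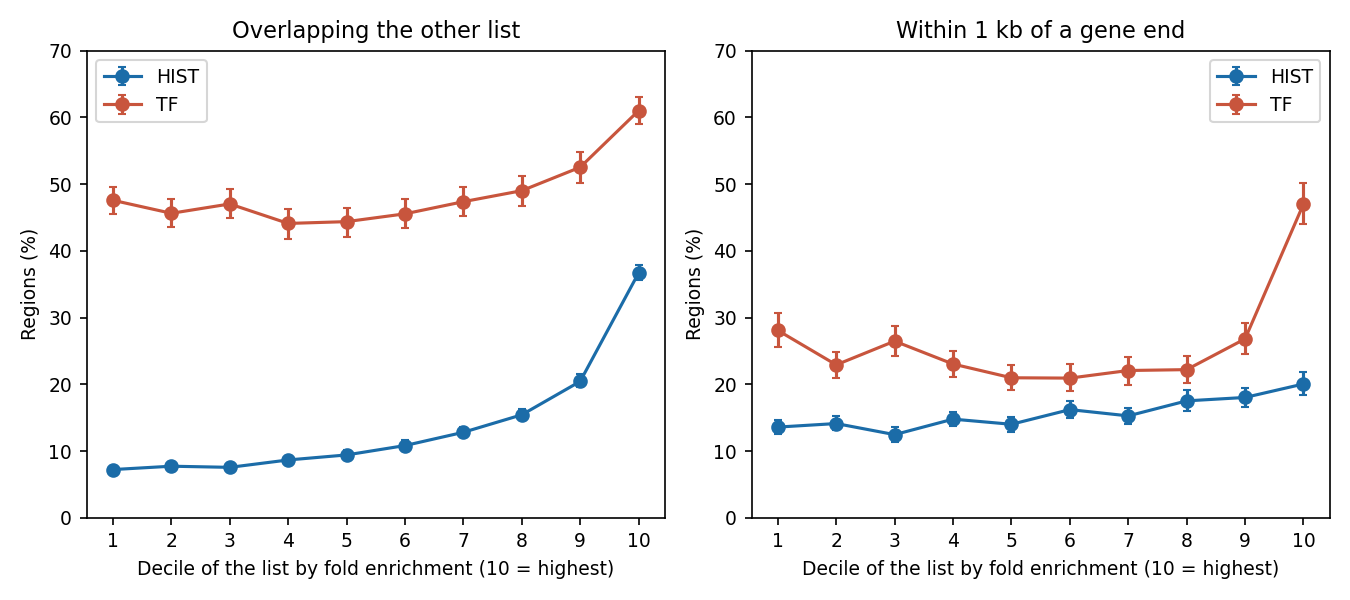
Share of regions (%) overlapping the other list (left) and within 1 kb of a gene end (right), by decile of fold enrichment within each list (10 is the highest), with 95% block-bootstrap intervals as bars. Gene ends made up 47.0% of the top TF decile, and the overlap of HIST regions with the TF list rose from 7.23% to 36.7%.

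Gene ends were most common in the TF decile with the highest fold enrichment, 47.0% (44.1 to 50.1), against 28.1% in the lowest decile and 20.9% in decile 6. HIST regions went from 13.6% in the lowest decile to 20.1% in the highest. Overlap with the TF list rose across the HIST deciles from 7.23% to 36.7%. Overlap of TF regions with the HIST list was 47.6% in the lowest decile and 61.0% in the highest. Region width, which also acts on overlap, was not matched across deciles.

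The fourth comparison asked which kinds of genes each library carried, over 21 gene lists fixed before the data were examined. Ribosomal protein genes were the list with the highest share of regions at gene ends in both libraries. Of 78, 68 (87.2%, exact 95% interval 77.7 to 93.7) had a HIST region and 60 (76.9%, 66.0 to 85.7) a TF region within 1 kb of an end, and 58 had both. Random lists of the same deciles of gene length averaged 43.4% and 25.4%, and the ribosomal list stood at percentile 100 of the 10000 random lists in both libraries. Of all 19126 autosomal protein-coding genes, 48.0% had a HIST region and 31.0% a TF region at an end. RPL23A had 12 HIST regions (4658 bp) and 6 TF regions (1915 bp), and the strongest TF region in or near RPL18 was 61.6-fold enriched. Genes of oxidative phosphorylation had 59 of 82 (72.0%) for HIST and 50 of 82 (61.0%) for TF, both at percentile 100. COX8A, a subunit of cytochrome c oxidase, had 6 HIST regions (1979 bp) and 3 TF regions (1275 bp). Proteasome subunit genes had 23 of 38 (60.5%, percentile 99.99) for TF and 24 of 38 (63.2%, percentile 96.5, inside the random range) for HIST, with the difference between libraries at percentile 97.4, also inside, but above it with the reduced HIST list (percentile 99.8). A 62.5-fold TF region lay in the window of PSMA2. These 3 lists had a high TF share of the covered sequence, 27.1% for ribosomal, 29.9% for oxidative phosphorylation and 33.3% for proteasome genes, against 18.4% over all genes (percentiles 99.8, 100 and 99.9; with 50-kb flanks the ribosomal list was inside the random range, at 92.8). HOX (34.3%, percentile 99.99), olfactory receptor (31.1%, percentile 100) and zinc finger genes (28.5%, percentile 100) had similar shares, HOX and olfactory genes with little sequence in either library (means of 61.36 and 17.72 bp for HIST, 32.0 and 7.98 bp for TF). Most of the HOX TF sequence was 1 region of 276 bp, counted in each of the windows of HOXA3, HOXA7, HOXA9 and HOXA10. The HOX share and its percentile therefore rest largely on that region. Cell cycle genes had 27 of 33 (81.8%, percentile 100) for HIST and 17 of 33 (51.5%, percentile 98.8) for TF, led by CCND2, a D-type cyclin, with 25 HIST regions (11672 bp).

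**Figure D3:**
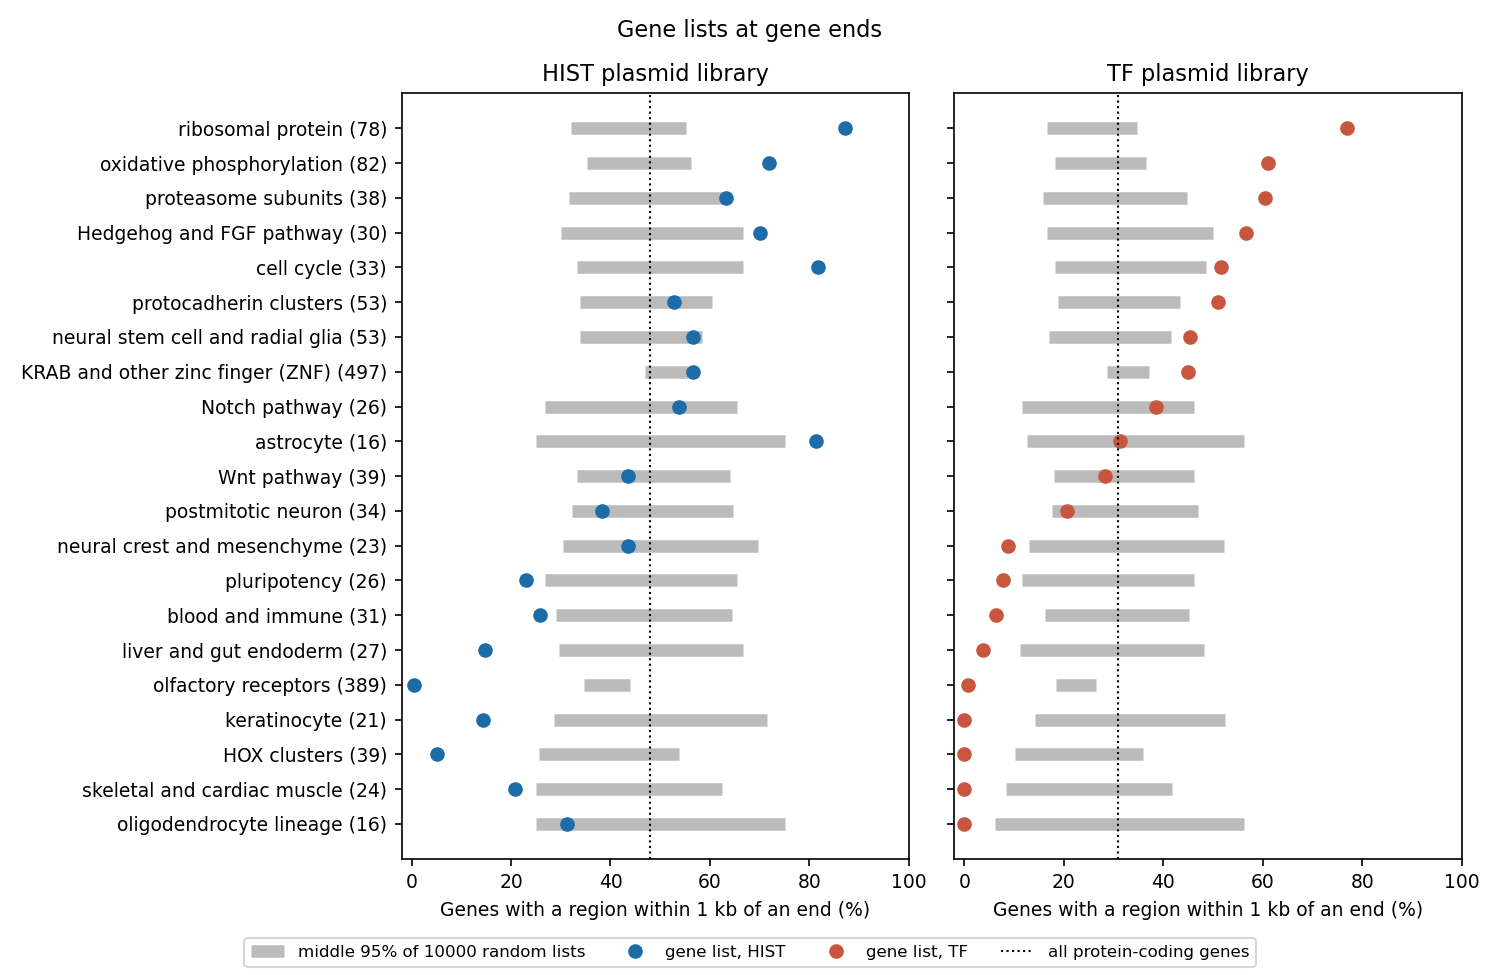
Share of the genes of each list (%, number of genes in brackets) with a HIST region (left) or a TF region (right) within 1 kb of an annotated gene end. Grey bars span the middle 95% of 10000 random lists of the same size and the same deciles of gene length. The dotted line marks all protein-coding genes (48.0% for HIST, 31.0% for TF). Ribosomal protein genes reached 87.2% and 76.9%.

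Neural stem cell and radial glia genes carried much more sequence than random genes in both libraries. The 53 genes averaged 5261 bp of HIST sequence in the gene and its 10-kb flanks, against 1766 bp in random lists, and 1132 bp of TF sequence against 391.5 bp, both at percentile 100. MSI2 led, and ZBTB16, a zinc finger transcription factor, had 95 HIST regions (36154 bp) and 15 TF regions (4510 bp). GLI3, an effector of Hedgehog signalling, had 54 HIST regions (15401 bp) and 13 TF regions (3881 bp). Without MSI2 the means were 4233 and 1043 bp, at percentiles 99.9 and 100. At gene ends, 24 of the 53 (45.3%, percentile 99.3) had a TF region and 30 (56.6%, percentile 94.1, inside the random range) a HIST region, and the difference between libraries stood at percentile 77.4, but at 99.6, above the range, with the 2.5-kb window. TCF7L2, a Wnt effector, and NR2F1 and ZIC1, transcription factors of the developing brain, were the members with a TF but no HIST region at an end. All 1417 TF bp at NR2F1 lay outside HIST regions, although 15 HIST regions (3882 bp) lay in the same window.

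Signalling pathways with roles in neural development also carried more sequence than random genes. These lists share members with the neural stem cell list, such as GLI3, NOTCH1 and TCF7L2, so they are not independent of it. Hedgehog and FGF genes averaged 5785 bp of HIST sequence against 1736 in random lists and 1156 bp of TF sequence against 387.2, with GLI2 at 108 HIST regions (47841 bp). Of the 30 genes, 21 (70%, percentile 98.8) had a HIST region and 17 (56.7%, percentile 99.6) a TF region at an end. PTCH1, the Hedgehog receptor, had a TF but no HIST region at an end, among 41 HIST and 9 TF regions in its window. Notch pathway genes averaged 3989 bp of HIST sequence against 1609 (percentile 99.4) and 633 bp of TF sequence against 361.4 (percentile 98.3), led by the co-activators MAML3, with 25896 HIST bp, and MAML2, with 21375. Wnt pathway genes averaged 3090 bp against 1592 (percentile 99.3) for HIST and 660.5 bp against 356.6 (percentile 99.9) for TF, led by TCF7L1 with 16284 HIST bp. At gene ends the Notch list (53.9% and 38.5%) and the Wnt list (43.6% and 28.2%) lay inside the random range for HIST and TF. The Notch TF excess was lost without MAML3 (percentile 86.5) and in the 50% of TF regions with the higher -log10 q (percentile 94.6).

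Of the lists of differentiated neural cells, only astrocyte genes differed between the libraries beyond the random range at gene ends. Astrocyte genes had a HIST region at an end in 13 of 16 cases (81.3%, percentile 99.5) and a TF region in 5 (31.3%, percentile 48.9), a difference of -50 points that stood at percentile 0.675. GFAP, the astrocyte filament gene, had 8 HIST regions (3042 bp) and 2 TF regions (338 bp). CLU, clusterin, had 7 HIST regions (3014 bp) and 2 TF regions (342 bp). In covered sequence the astrocyte list was inside the random range for HIST (percentile 54.1), for TF (15.1) and for the TF share of both (13.2%, percentile 11.3). Postmitotic neuron genes lay inside the random range, with 13 of 34 (38.2%) for HIST and 7 of 34 (20.6%) for TF. MAP2, a neuronal microtubule protein, had 8 regions in each library and slightly more TF (2335 bp) than HIST sequence (2213 bp). SNAP25, a synaptic SNARE protein, had 2 TF regions, up to 25.3-fold enriched, and no HIST region. None of the 16 oligodendrocyte lineage genes had a TF region at an end (percentile 0.135), and 5 (31.3%, percentile 9.30) had a HIST region, with the difference at percentile 15.1. Their covered sequence was inside the random range for HIST (1958 bp on average, percentile 90.8), for TF (234.2 bp, percentile 32.3) and for the TF share (10.7%, percentile 4.17). MYRF, a myelin regulatory factor, still had 24 HIST regions (10406 bp) in its window. The astrocyte HIST excess fell inside the random range with the 50% of regions with the higher -log10 q (percentile 95.1) and with the reduced HIST list (percentile 88.0, and 13.3 for the difference), whereas the neuron TF share fell below the range with the former (percentile 0.285).

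At gene ends, genes of other lineages mostly stood below random genes. No TF region lay at an end of any of 24 muscle genes (percentile 0.03) or 21 keratinocyte genes (percentile 0.005), and 1 of 27 liver and gut genes (3.70%, percentile 0.075) and 2 of 31 blood and immune genes (6.45%, percentile 0.07) had one. HIST regions lay at ends of 5 of 24 muscle (20.8%, percentile 1.40), 3 of 21 keratinocyte (14.3%, percentile 0.045), 4 of 27 liver and gut (14.8%, percentile 0.015) and 8 of 31 blood genes (25.8%, percentile 0.76). MYH7, a cardiac myosin, held 5414 bp of HIST sequence in 11 regions and was the muscle gene with the most TF sequence, 182 bp. Pluripotency genes had 6 of 26 (23.1%) for HIST and 2 of 26 (7.69%) for TF, both at percentile 0.59. DNMT3B, a DNA methyltransferase, and LIN28A, an RNA-binding protein, had the most sequence among them, with 16 and 11 HIST regions and 5 and 6 TF regions. Neural crest and mesenchyme genes were inside the random range for HIST, with 10 of 23 (43.5%, percentile 29.5), and below it for TF, with 2 of 23 (8.70%, percentile 0.56), while the difference itself, at percentile 5.07, was inside it, but below it with the 2.5-kb window (percentile 0.24). In covered sequence, the HIST means were inside the random range for pluripotency (percentile 8.71), neural crest (80.0), muscle (2.71) and blood genes (10.5), and below it for liver (0.07) and keratinocyte genes (0). The TF means were inside it for pluripotency (6.86) and neural crest genes (4.84), and below it for muscle (0), liver (1.90), blood (1.05) and keratinocyte genes (0.01). The TF share of the covered sequence was below it for neural crest genes (9.35%, percentile 0.54; inside, at 14.5, without the member with the most sequence) and muscle genes (1.55%, percentile 0; inside, at 3.25, with 50-kb flanks). It was inside it for pluripotency (percentile 42.3), liver (92.6), blood (10.4) and keratinocyte genes (68.3, but above it, at 99.55, with the reduced HIST list). Without the member with the most sequence, the HIST means of pluripotency (1.10), blood (0.71) and muscle genes (0.12) and the TF mean of pluripotency genes (0.95) fell below it. With 50-kb flanks the TF means of pluripotency (1.02) and neural crest genes (0.26) fell below it and that of muscle genes came inside (3.06), and with the 50% of higher -log10 q that of neural crest genes fell below (1.71) and that of liver genes came inside (7.52). With unmatched random lists, muscle HIST (0.34) and pluripotency TF means (2.18) fell below it. PDGFRB, a receptor of pericytes and mesenchyme, had 34 HIST regions (14345 bp) and 1 TF region (171 bp). The liver HIST share was inside the random range with the reduced HIST list (percentile 6.33), the muscle HIST share was just inside it with the 2.5-kb window (percentile 2.51), and the pluripotency TF share was inside it with the 50% of regions with the higher -log10 q (percentile 6.86).

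Gene families, many of them in clusters, differed from each other. The zinc finger list was not limited to clustered genes, and held for example ZNF423 on chromosome 16 and ZNF362 on chromosome 1. Zinc finger (ZNF) genes had a TF region at an end in 223 of 497 cases (44.9%, percentile 100) and a HIST region in 281 (56.5%, percentile 99.4), and the TF minus HIST difference stood at percentile 99.9. Their windows held more TF sequence than random lists, 362.4 bp on average against 292.9 (percentile 99.96), and less HIST sequence, 908.9 bp against 1276 (percentile 0). ZNF585B had 4 TF regions, up to 57.7-fold enriched, and 2 HIST regions, with 1273 of its 1507 TF bp outside HIST regions. ZNF423, by contrast, had 109 HIST regions (41584 bp) and 11 TF regions (2930 bp). Clustered protocadherin genes, which give neurons cell-surface identity, had 27 of 53 (50.9%, percentile 99.8) for TF and 28 of 53 (52.8%, percentile 81.8) for HIST, with the difference at percentile 96.8. The HIST share rose above the random range with the 50% of regions with the higher -log10 q (percentile 98.95) and the reduced HIST list (99.98), and the difference with the 2.5-kb window (99.65) and unmatched lists (98.56). PCDHB7 and PCDHB16 shared a pair of TF regions and had no HIST region. PCDHGA1, PCDHGA10, PCDHGA11 and PCDHGA12 shared 1 annotated end, at 141512975, and each had both kinds of region at an end. The protocadherin counts of 27 and 28 may therefore hold 1 gene end several times, and their percentiles may rest largely on it. HOX genes had HIST regions at ends of 2 of 39 and TF regions at none, both at percentile 0, and a 25.4-fold TF region was shared by the windows of HOXA3, HOXA7, HOXA9 and HOXA10. Of 389 olfactory receptor genes, 2 had a HIST and 3 a TF region at an end (0.514% and 0.771%, percentile 0 for both). Random lists treat genes as independent, so the percentiles of clustered families, whose members share regions, understate their spread. They were also not matched on chromosome, and chromosome 19, which holds ZNF585B, had the most TF regions per Mb (15.5). The ZNF excess of HIST regions at ends fell inside the random range with the 50% of regions with the higher -log10 q (percentile 93.2) and the reduced HIST list (91.0), and the excess of TF sequence without length matching (90.2).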

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

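Of the tests below, those of gene ends and of shared high-signal regions for the overlap, and that of the list length for the gene end difference, were chosen only after the result was seen, and the moves by up to 1 Mb, the 200-bp windows and the reduced HIST list were added after seeing the data.

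Regions outside the chromosomes that entered the comparisons were looked at because no comparison used them. The TF list held 7 regions on the mitochondrial genome, with fold enrichment from 1.59 to 3.0, and the HIST list held 0. On unplaced or alternate sequences the HIST list held 34 regions (9863 bp) and the TF list 48 (11233 bp), with fold enrichment of up to 23.8 and 21.8.

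TF regions overlapped HIST regions in 48.4% of cases against 1.84% of placements. If both lists only lay in the same broad gene-rich stretches, TF regions moved by up to 1 Mb would overlap about as often, but overlap in place was 17.1 times that of moved regions (2.84% ± 0.109). If both only lay at gene ends, TF regions elsewhere would not overlap in excess, but they did so 18.9 times as often as moved ones (46.5% against 2.46%). Shared high-signal artefact regions could not be tested: the lowest TF decile by fold stood at 25.8 times the mean of placements, but fold is a ratio over the background, so an artefact locus can have a low fold, and no list of such regions and no read signal was used here. Binding of SOX2 and YY1 within marked chromatin remains as a hypothesis that these lists do not test, and fragments common to both ChIP preparations for other reasons, such as open chromatin, may also contribute.

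The other 51.6% of TF regions, 12190, overlapped no HIST region. A candidate explanation is a HIST list that was not exhausted at the authors' threshold. The weakest decile of HIST regions still added 1.89 percentage points of TF overlap against 0.0749 for random placements of them, a ratio of 25.3. HIST regions as a whole overlapped TF regions 27.1 times as often as placements, so such a ratio cannot decide this. As deciles of the HIST list were added down to the weakest, the gain fell from 15.1 to 1.89 points. What still weaker regions would add is unknown. A TF site in a gap between flanking HIST regions would leave a HIST region within 1 kb on both sides; 16.2% of the TF regions without overlap had this, so gaps of this kind leave most of them unexplained, although moved regions had it in only 0.555%. A HIST region within 1 kb on either side was present for 50.2%, against 5.44% of moved ones. TF binding outside H3K27ac and H3K4me1 chromatin, at SNAP25 for example, where the window held no HIST region, stays open, since depth is unknown.

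TF regions lay at gene ends more often than HIST regions by 10.5 points. A longer HIST list reaching weaker regions accounts for part of this at most, since the difference stayed at 5.94 points (5.02 to 6.87) with HIST reduced to the TF number. A different smallest width does not account for it, since the difference was 10.8 points (10.0 to 11.6) for 200 bp around each summit. YY1 binding at promoters is a hypothesis for the TF library that may fit the gene end share of the strongest TF decile, 47.0%. It concerns only the TF side of the difference. The lists do not separate SOX2 from YY1 fragments, nor H3K27ac from H3K4me1 fragments. Neither this hypothesis nor a part played by the HIST mix was tested.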

How the results depend on the processing

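No paired analysis was possible because each library has 1 list whose columns carry no replicate, which also ruled out leaving out replicates. Motif content and its alternatives were not run. Merging regions first changed nothing, since no regions of a list overlap. With regions of at least 200 bp the TF list held 14415 regions instead of 23638, and with the reduced HIST list there were 12471 HIST clusters instead of 29305, both by construction. The intergenic difference fell to 0.177 points in bp, interval -0.770 to 1.15, and grew to 3.95 points (2.86 to 5.04) with the reduced HIST list. The cause was not tested. Overlap stayed above its placements, and the gene end and gene body differences kept their direction with intervals clear of 0, under all alternatives run. Of the counts of gene lists beyond the random range, those for gene ends and covered sequence in either library stayed within 1.5 times under all alternatives but one: without the member with the most sequence, chosen after seeing the data, 8 instead of 5 lists were below the range for HIST sequence, since a single gene such as DNMT3B or CD4 had held up a mean. Counts for the TF minus HIST difference rested on few lists: with the 2.5-kb window 4 instead of 2 were above and 2 instead of 1 below, 3 were below with the 50% of higher −log10 q, and with the reduced HIST list, chosen after seeing the data, 4 were above and 0 below. For the TF share of sequence, 1 instead of 2 lists was below with 50-kb flanks and without the top member. The cause of these was not tested. Of 525 percentiles of single lists under alternatives, 475 stayed on their side of the limits, 24 fell inside them, 23 moved outside and 3 changed direction. These were ribosomal HIST sequence without length matching (percentile 49.7 from 99.95), the ribosomal difference with the 50% of higher −log10 q (1.25 from 93.4) and the olfactory difference with the reduced HIST list (17.4 from 100). Few olfactory genes had a region at an end in either library (0.514% for HIST, 0.771% for TF). Their difference was thus 0.257 points against -16.96 in random lists, so its percentile of 100 reflects scarce regions. Unknown depth limits every statement that a region is missing from a list.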

Other observations

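By rank, gene-dense chromosomes held relatively more HIST regions. Chromosome 22 had 51.8 HIST and 8.89 TF regions per Mb, a ratio of 5.82, and chromosome 4 had 18.4 and 6.60, a ratio of 2.78. Chromosome 19, with the most genes per Mb, had a ratio of 3.87. Across the 22 autosomes the ratio rose with genes per Mb by rank (Spearman's rho 0.709, two-sided permutation p = 0.00034), while Pearson's r was 0.384 (permutation p = 0.0736). Without chromosomes 17 and 19, the most gene-dense, r was 0.695 and rho 0.683. This relation was chosen after seeing the data, so its p-values are descriptive only.

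Some regions were unlike the rest of their list. Of the 10 TF clusters with the most sequence, several had no protein-coding gene, among them 46380846 to 46401627 (14 regions) and 34571638 to 34593312 (10 regions) on chromosome 16. Whether such clusters are high-signal artefacts was not tested. A TF region at 113305610 to 113306235 on chromosome 2 was 79.3-fold enriched, overlapped a HIST region and lay 27001 bp from the nearest protein-coding gene end, that of PAX8. Whether that region is an artefact was not tested either. Within the HIST list, the regions that overlapped the TF list were wider (median 348 against 243 bp) and stronger (median fold 6.24 against 5.08) than those that did not. Within the TF list the gap was smaller, 261 against 204 bp and 6.77 against 6.39. A wider region overlaps more readily when 1 bp is enough, and widths were not matched, so part of the width gap follows from the rule.

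Of all 19126 genes, 4853 had both kinds of region at an end, 4318 only HIST, 1073 only TF and 8882 neither. Among oxidative phosphorylation genes, NDUFA9 and UQCRFS1 were in the TF-only class, with 33.9-fold and 6.07-fold TF regions in their windows. Among Wnt genes, LGR4, a receptor, was in that class, with 7 TF and 17 HIST regions in its window.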
